A study of Mus musculus with 6 samples.

How the data were processed

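RNA was measured in 6 libraries of NK cells sorted from the spleens of C57BL/6 mice on day 2 after an intraperitoneal dose of 200 µg of poly(I:C). Per the labels, 3 libraries came from CD11b+ LAG3+ cells and 3 from CD11b+ LAG3- cells, each from a pool of 10 spleens, and the 6 share 1 batch label. The labels' protocols describe total RNA from a GenElute Mammalian Total RNA Miniprep kit, selection of polyadenylated RNA with poly-T beads, random priming, dUTP in the synthesis of complementary DNA, and strand-specific libraries. The labels number the replicates 1 to 3 in both fractions and do not say whether a LAG3+ and a LAG3- library of 1 number came from the same pool of spleens.

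The authors deposited a table of TPM, listed for 21234 gene symbols, with 1 column per library. TPM divides reads by transcript length and scales each library to the same total, so it keeps relative abundance within a library and no depth. The columns summed to between 984786 and 986849 TPM. The submitters' processing notes name kallisto 0.45.0, DESeq2 1.44.0 and the genome build GRCm38; kallisto assigns reads to transcripts by pseudoalignment, and reads shared by near-identical genes are divided between them by estimation. The annotation, the strand setting, the sequencing depth and how transcripts were summed to genes are not given in the sources used here. DESeq2 was not run here, because it needs counts. All 6 columns of the table were matched to samples by the column names in the labels.

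Each gene with a mean of at least 1 TPM over the 6 libraries was tested, 11354 in all. Values were transformed to log2(TPM + 1), so a fold change is on the log2(value + pseudocount) scale and understates the change of genes with low TPM. The test was limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, no covariate, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The prior had 3.36 degrees of freedom beside 4 residual ones. Means are given ± SD over 3 libraries of a fraction. P-values measure the spread between libraries, each made from a pool of 10 spleens. Tables were also handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

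The test, the 36 gene lists, the rule for named genes and the processing alternatives were fixed before the data were examined, except where the text says otherwise. Of the lists, 34 had at least 3 tested members and were tested with camera at a preset correlation of 0.01 with adjustment over the lists, with camera at a correlation estimated from the data, and with fry. Camera compares a list with the other genes. Lag3 was in no list. Within each list, genes were also adjusted over the list alone. At the preset correlation 18 lists passed; in the other splits of the 6 libraries into 3 and 3, up to 16 did. Lists of markers of B cells, plasma cells, T cells, monocytes and macrophages, neutrophils, dendritic cells, erythroid cells, platelets, mast cells and endothelium covered cells a splenic sort could hold.

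Genes are named by these rules: Lag3; 16 fixed genes whatever their result (Itgam, Cd27, Klrg1, Ncr1, Klrb1c, Ifng, Gzmb, Prf1, Il12rb2, Pdcd1, Tigit, Havcr2, Tox, Eomes, Tbx21 and Mki67); the 12 largest and 12 smallest log2 fold changes among genes past the threshold whose fractions did not overlap, leaving out immunoglobulin and T cell receptor segments, predicted genes and pseudogenes; up to 4 members of each list past the threshold with the smallest p, or 2 given as values where none passed; and the 2 members of each marker list with the highest mean TPM. This named 124 genes. Gene positions are those of GENCODE M21 on GRCm38, which held 19614 of the 21234 symbols; the other 1620 have no position here. Transcript length and GC content from the same annotation were known for 10885 genes tested, or 95.9%.

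The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrial, ribosomal protein, immunoglobulin and haemoglobin genes, no intensity trend, a robust variance prior, limma's library weights, the replicate number as a block, and each library left out in turn. A correction for transcript length and GC content was added after the data were seen. The procedure was tested on simulated libraries with 11354 genes and the spread of these data: 31.3% of genes changed 1.5-fold, 55.2% of genes changed 2-fold and 92.4% of genes changed 4-fold were recovered, and 6 of 125 calls were false. With no gene changed, 0 genes were called. Many changes of 1.5-fold would therefore be missed with 3 libraries per fraction. The simulated noise was independent between genes, so it held no shift of a whole library such as that of LAG3+ replicate 2. The changed genes were drawn from those at about 5 TPM or more. The recovered shares and false calls therefore do not describe weaker genes or data with such a shift.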

Results

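Gene expression was measured by RNA sequencing in natural killer (NK) cells of C57BL/6 mice, an inbred laboratory strain. NK cells are innate lymphocytes that kill target cells and secrete cytokines. The mice had received 200 µg of poly(I:C), a synthetic double-stranded RNA that mimics viral RNA, by injection into the peritoneum. On day 2, NK cells carrying CD11b, an integrin chain encoded by Itgam and typical of mature NK cells, were sorted from the spleen into a LAG3+ and a LAG3- fraction. LAG3 is an inhibitory surface receptor that binds MHC class II. Each fraction had 3 libraries, and each library came from a pool of 10 spleens. The values are TPM, transcript abundances scaled to a fixed total per library, listed for 21234 gene symbols in 6 libraries that summed to between 984786 and 986849 TPM. TPM keeps no sequencing depth, so the depth of these libraries is unknown and no counting interval can be given. The series title describes LAG3 as a mark of NK cells that are activated but respond poorly, and the comparison of the 2 fractions asks which transcripts differ between them.

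Transcripts of the sort marker itself separated the fractions. Lag3 reached 64.3 ± 6.24 TPM (SD, n = 3) in LAG3+ cells and 8.57 ± 4.00 TPM in LAG3- cells, a 7.51-fold ratio of means. Its 3 LAG3+ libraries held 70.5, 58.0 and 64.3 TPM, and its 3 LAG3- libraries held 13.2, 5.82 and 6.72 TPM. The log2 fold change on the log2(TPM + 1) scale was 2.84 (SE 0.26, limma adjusted p = 0.0032), which checks the labels and is no finding about the cells. Lag3 (ENSMUSG00000030124.2) lies on the minus strand of chromosome 6 from 124904361 to 124911705 in GRCm38. Beyond the sort marker, lists of early-maturation, innate lymphoid cell type 1 (ILC1), cell cycle, ribosome biogenesis and MHC class II genes lay higher in LAG3+ cells by camera at a preset correlation, and lists of late-maturation, homing, activating receptor and cytotoxic granule genes lay lower. With an estimated correlation the late-maturation list kept its call (adjusted p = 0.042), while MHC class II genes (adjusted p = 0.26) and the other lists named here (adjusted p = 0.29 for each) lost it. In all, 377 genes were higher and 384 lower in LAG3+ cells among 11354 tested, of which 92 were at least 2-fold higher and 78 at least 2-fold lower.

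Among the largest increases were genes of signalling receptors and transcription factors. Gpr55, a G protein-coupled receptor for lysophospholipids, rose from 0.503 ± 0.200 to 15.3 ± 5.69 TPM, with a log2 fold change of 3.39 (SE 0.27, adjusted p = 0.0020), and lies on chromosome 1 from 85938318 to 85961007. P2rx7, an ATP-gated cation channel, rose by 2.87 on the log2 scale, from 0.819 ± 0.266 to 13.2 ± 6.33 TPM. The Notch ligand gene Dll1 rose from 1.198 ± 0.210 to 13.6 ± 4.07 TPM and the AP-1 family transcription factor gene Batf3 from 2.73 ± 0.921 to 19.7 ± 5.52 TPM. Id3, an inhibitor of E-protein transcription factors, rose by 2.11 and the tetraspanin gene Cd63 by 2.32 on the log2 scale. Cd22, which encodes a sialic acid-binding inhibitory receptor best known from B cells, rose from 39.3 ± 4.56 to 154 ± 34.1 TPM. Asb2, Trat1, Adgrg5 and Klk8 rose by 1.95, 1.94, 1.93 and 1.75. Of these genes, Asb2, Trat1 and Id3 no longer passed with 1 LAG3- library left out, while Lag3, Gpr55, P2rx7, Dll1, Batf3, Cd63, Cd22, Adgrg5 and Klk8 passed with each library left out in turn.

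Among the largest decreases was Kcnj8, a subunit of an ATP-sensitive potassium channel, which fell from 19.2 ± 3.68 to 2.85 ± 0.713 TPM, a log2 fold change of -2.39 (SE 0.20, adjusted p = 0.0024). It lies on chromosome 6 from 142564837 to 142571614. Mcam, an adhesion molecule of the immunoglobulin family, fell from 46.9 ± 3.73 to 9.67 ± 0.680 TPM (log2 fold change -2.16, SE 0.11). Cma1, a chymase gene listed among late-maturation NK cell genes, fell from 330 ± 15.0 to 87.9 ± 15.2 TPM. Ly6c2 fell from 531 ± 28.4 to 157 ± 18.5 TPM and its relative Ly6a2 from 50.2 ± 3.98 to 13.7 ± 1.22 TPM; these belong to a family of similar genes whose reads can be split between copies. Dennd2b, Cdh22, Dhrs3 and Rhpn1 had log2 fold changes of -2.05, -2.00, -1.82 and -1.81. Gp1bb, a platelet glycoprotein gene, fell from 4.68 ± 1.34 to 0.907 ± 0.386 TPM, and it no longer passed without LAG3- replicate 2 or 3.

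**Figure D1:**
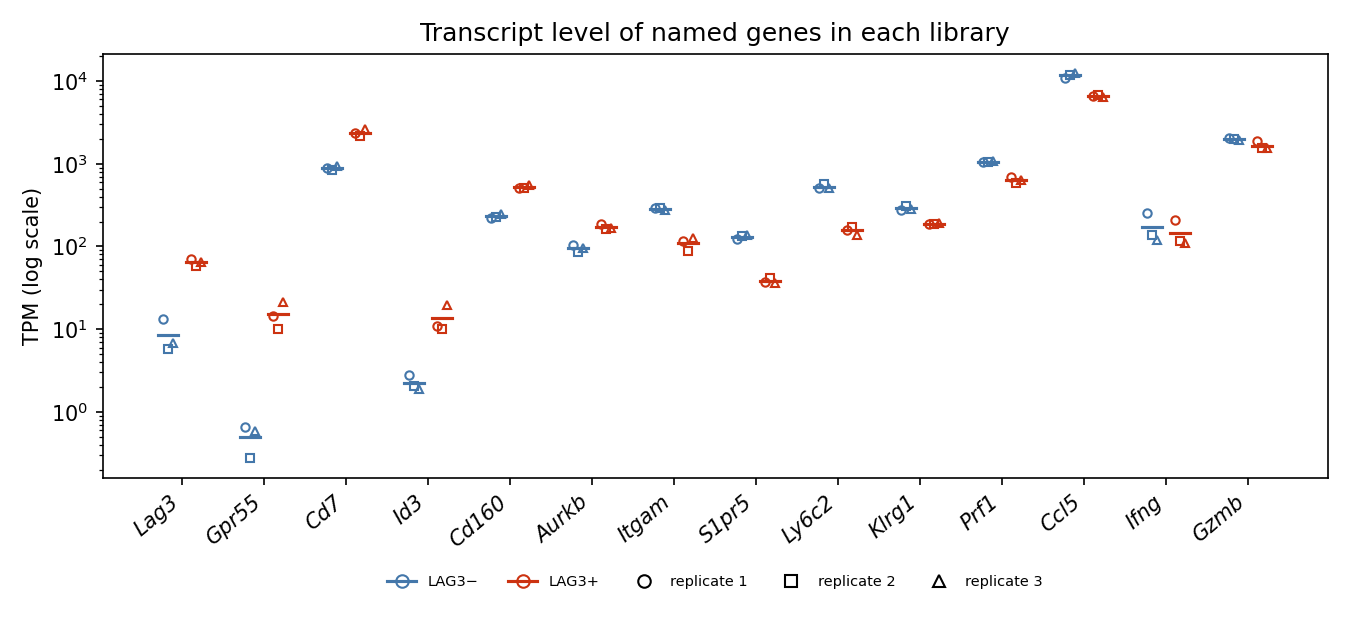
TPM on a log axis for 14 named genes in each of the 3 LAG3- (blue) and 3 LAG3+ (red) libraries, with symbols for the replicate number and lines at the group means. Lag3 lies between 58.0 and 70.5 TPM in the LAG3+ libraries and at most at 13.2 TPM in the LAG3- libraries, while Ifng and Gzmb did not pass the test.

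All 12 tested late-maturation NK cell genes lay lower in LAG3+ cells, 9 passed the test, and 9 passed when adjusted over the list alone. Itgam, which lies on chromosome 7 from 128062640 to 128118491, fell from 287 ± 7.18 to 110 ± 20.1 TPM within cells sorted for its protein (log2 fold change -1.39, SE 0.14, adjusted p = 0.0035). S1pr5, a sphingosine 1-phosphate receptor needed for exit of NK cells from lymphoid organs, fell from 131 ± 7.97 to 38.5 ± 3.16 TPM. Klrg1, an inhibitory receptor of mature NK cells, fell from 288 ± 16.2 to 189 ± 3.59 TPM. The list as a whole was lower than other genes by camera (adjusted p = 2.0e-13), and it was the 1 list whose call held with an estimated correlation (adjusted p = 0.042). Between 4 and 10 members passed with single libraries left out, the fewest without LAG3- replicate 2 or 3. Monocyte and macrophage markers, a cell type that also holds Itgam, Ly6c2, Cx3cr1 and Zeb2, lay in the same direction, with a sum of 88.9 ± 9.01 against 142 ± 6.03 TPM. Homing and adhesion genes overlapped with this group: 7 of 21 fell (2 rose and 9 fell adjusted over the list alone), among them the fractalkine receptor gene Cx3cr1 (from 16.2 ± 3.52 to 4.63 ± 1.64 TPM). That list was lower by camera (adjusted p = 1.2e-05) but not with an estimated correlation (adjusted p = 0.29), and 3 to 8 members fell with single libraries left out; without LAG3+ replicate 2, 4 rose and 8 fell. Itgam, S1pr5, Ly6c2 and Cma1 passed with each library left out in turn; Klrg1 did not pass without LAG3- replicate 2 or 3, nor Cx3cr1 without those or LAG3+ replicate 1.

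Of 16 early-maturation genes, 13 lay higher and 3 lower in LAG3+ cells; 4 rose, and 11 rose adjusted over the list alone. They were Cd7 (from 883 ± 44.5 to 2380 ± 215 TPM), Id3, Slamf6 (from 11.6 ± 2.25 to 26.1 ± 5.48 TPM) and the lymphotoxin gene Ltb (from 36.3 ± 1.27 to 63.3 ± 15.6 TPM). Cd27, whose protein marks less mature NK cells, was 163 ± 9.55 against 135 ± 6.31 TPM and did not pass (adjusted p = 0.11). All 12 tested ILC1 genes lay higher; 4 rose, and 11 rose adjusted over the list alone. Besides Gpr55 they were Tnfsf10, which encodes the death ligand TRAIL (from 5.67 ± 0.854 to 18.7 ± 6.81 TPM), the cytokine receptor gene Il21r (from 25.5 ± 3.30 to 49.2 ± 7.40 TPM) and Zfp683, which encodes the transcription factor Hobit (from 1.38 ± 0.144 to 7.46 ± 5.09 TPM). Both lists were higher by camera, with adjusted p of 1.2e-05 and 3.0e-07, and neither call held with an estimated correlation (adjusted p = 0.29 for both). Without LAG3+ replicate 2, 12 early-maturation and 12 ILC1 genes rose, and as few as 1 of each rose with other single libraries left out. The sum of T cell markers lay higher beside these lists, at 1457 ± 129 against 1049 ± 53.5 TPM, but most of it was Trbc1 and Trbc2. Cd3g was 71.3 ± 2.34 against 23.2 ± 2.93 TPM. Cd3d was higher too, at 52.7 ± 8.67 against 20.1 ± 5.12 TPM. Some other T cell markers differed little or lay lower. Trac was 24.1 ± 2.30 against 22.7 ± 4.63 TPM (limma adjusted p = 0.79), Cd3e 7.90 ± 2.25 against 6.84 ± 0.951 TPM and Trdc 28.2 ± 0.337 against 37.1 ± 1.77 TPM. Cd7 and Gpr55 passed with each library left out in turn, unlike Slamf6, Ltb, Tnfsf10, Il21r, Zfp683 and Id3.

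Among transcription factors of NK cell identity, 1 of 15 rose and 3 fell (1 and 4 adjusted over the list alone). Zeb2, a repressor required for terminal NK cell maturation, fell from 45.0 ± 2.29 to 17.1 ± 4.92 TPM (log2 fold change -1.38, SE 0.21, adjusted p = 0.013). The T-box factor genes Tbx21 and Eomes fell from 299 ± 10.3 to 211 ± 6.84 TPM and from 205 ± 7.75 to 146 ± 16.8 TPM, and Zfp683 rose. The camera call of this list (lower, adjusted p = 0.037) was lost with an estimated correlation (adjusted p = 0.73) and without LAG3+ replicate 2 (adjusted p = 0.31), when 4 members rose and 3 fell. All 4 of these calls ended without at least 1 of the LAG3- libraries. Of 13 transcription factors of lymphocyte exhaustion and activation, 1 rose, also adjusted over the list alone: Irf4, a factor induced by antigen receptor signals in lymphocytes, went from 3.25 ± 0.554 to 9.002 ± 2.06 TPM. That list did not pass (adjusted p = 0.14), and Tox, a regulator of T cell exhaustion, was 19.2 ± 5.66 against 13.3 ± 1.59 TPM (adjusted p = 0.24). Between 0 and 5 of its members rose with single libraries left out, 5 of them without LAG3+ replicate 2, and Irf4 did not pass in the remaining cases.

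Effector and receptor genes were in part lower. Of 17 cytotoxic granule and death-ligand genes, 5 fell and 3 rose (7 and 3 adjusted over the list alone). Prf1, which encodes the pore-forming protein perforin, fell from 1057 ± 19.0 to 633 ± 52.1 TPM (log2 fold change -0.74, SE 0.09, adjusted p = 0.0061), the serpin protease inhibitor gene Serpinb9b fell from 99.0 ± 1.80 to 46.1 ± 4.33 TPM, and the lysosomal protease gene Ctsd fell from 1398 ± 70.0 to 879 ± 20.2 TPM. Gzmc, a granzyme gene, rose from 4.87 ± 0.760 to 11.1 ± 1.34 TPM. Gzmb, which encodes granzyme B, was 1659 ± 207 against 1992 ± 49.3 TPM and did not pass (adjusted p = 0.18). Of 15 activating NK receptors and adaptors, 5 fell and 1 rose (8 and 2 adjusted over the list alone). They included Klrb1c, which encodes NK1.1 (from 845 ± 48.6 to 515 ± 34.2 TPM), Cd2 (from 474 ± 31.6 to 279 ± 22.5 TPM), the Fc receptor gene Fcgr3 (from 120 ± 6.54 to 79.7 ± 2.03 TPM) and Cd247, the zeta chain adaptor (from 243 ± 3.37 to 171 ± 8.88 TPM). Ncr1, which encodes the receptor NKp46, was 836 ± 100.1 against 984 ± 70.8 TPM (adjusted p = 0.25). Of 9 genes of the Ly49 receptor family, many of whose members bind MHC class I, 3 fell, also adjusted over the list alone. They were Klra9, Klra8 and Klra4, with log2 fold changes of -0.92, -0.73 and -0.70; these genes resemble one another, so their reads can be split between copies.

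The cytotoxic and activating receptor lists were lower by camera, with adjusted p of 0.00022 and 0.00015, and neither call held with an estimated correlation (adjusted p = 0.29 for both). The Ly49 list was lower by camera (adjusted p = 0.016), but not with an estimated correlation (adjusted p = 0.64). Its call also ended with no filter on low values, where the median of its members turned to 0.0081 (adjusted p = 0.063). With single libraries left out, 1 to 7 cytotoxic genes and 1 to 7 activating receptor genes fell, most of them without LAG3+ replicate 2. Of the 6 libraries left out in turn, genes of these lists also rose only without that library, 3 of each list. Klrb1c, Serpinb9b, Klra8 and Klra9 passed with each library left out in turn. Prf1 and Ctsd did not pass without LAG3- replicate 3, Cd2 and Fcgr3 without LAG3- replicate 2 or 3, and Gzmc, Cd247 and Klra4 without any 1 of the LAG3- libraries.

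Inhibitory receptors other than LAG3 moved both ways. Of 15 tested, 2 rose and 2 fell (3 and 4 adjusted over the list alone). Cd160, which binds the receptor HVEM, rose from 232 ± 13.0 to 522 ± 25.2 TPM (log2 fold change 1.17, SE 0.08, adjusted p = 0.0014), and Havcr2, which encodes TIM-3, rose from 4.41 ± 0.691 to 9.51 ± 2.28 TPM. Klrg1 and Entpd1, which encodes the ATP-hydrolysing enzyme CD39, fell. Tigit was 122 ± 16.5 against 155 ± 11.1 TPM (adjusted p = 0.14). Pdcd1, which encodes PD-1, lay below the expression filter, at 0.247 ± 0.0730 TPM in LAG3+ cells and listed at 0 in the 3 LAG3- libraries. The list did not pass by camera (adjusted p = 0.63); its median log2 fold change was -0.045 and its mean 0.087. With single libraries left out, 1 to 3 members rose and 0 to 2 fell. Cd160 passed with each library left out in turn, while Havcr2 and Entpd1 passed without LAG3+ replicate 2 but not without any other library.

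Cytokine genes and their receptors gave no list-wide difference. Of 13 cytokine and chemokine genes, Ltb rose and Ccl5 fell (4 and 2 adjusted over the list alone). Ccl5, a chemokine among the most abundant transcripts here, was 11722 ± 777 TPM in LAG3- and 6556 ± 155 TPM in LAG3+ cells (log2 fold change -0.84, SE 0.09, adjusted p = 0.0054). Ifng, the main cytokine of NK cells, was 145 ± 54.0 against 170 ± 70.9 TPM (adjusted p = 0.77). Of 25 cytokine receptors, kinases and STATs, 4 fell and 1 rose (9 and 3 adjusted over the list alone). Both chains of the IL-18 receptor were among the lower genes, Il18rap from 251 ± 30.5 to 134 ± 21.7 TPM and Il18r1 from 114 ± 17.5 to 64.3 ± 13.4 TPM, as was Ifngr1 (from 313 ± 11.4 to 195 ± 17.6 TPM). The IL-12 receptor gene Il12rb2 was 75.5 ± 20.5 against 115 ± 7.69 TPM and did not pass (adjusted p = 0.11). Camera gave adjusted p of 0.24 for the cytokines and 0.096 for the receptors; the receptor list passed as lower with no filter on low values (0.037), at a mean TPM of at least 5 (0.033), and without LAG3+ replicate 1 (0.038) or 3 (0.030). Without LAG3+ replicate 2, 8 receptor genes rose and 8 fell, and without any 1 of the LAG3- libraries none passed. Ccl5 passed with each library left out in turn but not with no filter on low values.

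Genes of proximal receptor signalling and of its negative regulators gave no call in the limma test among 22 and 21 tested members, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 3 of the first and 2 of the second list were lower and 0 higher. The members with the smallest p were Prkcq (96.1 ± 13.0 against 132 ± 5.95 TPM, adjusted p = 0.061) and Txk (148 ± 15.2 against 185 ± 4.02 TPM), and among negative regulators Socs2 and Pdcd4 (adjusted p = 0.18 and 0.20). Camera gave adjusted p of 0.24 and 0.81; for the negative regulators the median (-0.0019) and the test pointed down and the mean (0.022) up. Without LAG3+ replicate 2, 2 signalling genes were called higher and 2 lower, and 3 negative regulators were called higher.

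Genes of cell division and growth lay higher in LAG3+ cells, though part of them did not pass. All 25 tested G2 and mitosis genes lay higher in LAG3+ cells; 14 rose, and 22 rose adjusted over the list alone. The mitotic kinase gene Aurkb rose from 95.3 ± 9.80 to 173 ± 13.3 TPM (log2 fold change 0.86, SE 0.11, adjusted p = 0.0073), Aurka from 34.5 ± 1.439 to 59.7 ± 3.52 TPM, Cdk1 from 206.0 ± 11.2 to 326 ± 28.7 TPM and the cyclin gene Ccnb1 from 53.5 ± 4.56 to 88.8 ± 9.83 TPM. All 27 tested DNA replication and S phase genes lay higher; 8 rose, and 18 rose adjusted over the list alone. They included the nucleotide metabolism genes Dut, Tk1, Rrm2 and Rrm1, with log2 fold changes of 0.49, 0.64, 0.65 and 0.42. Mki67, which encodes the proliferation marker Ki-67, was 202 ± 57.7 against 150 ± 14.5 TPM and did not pass (adjusted p = 0.35). All 24 tested genes of the list of MYC targets, ribosome biogenesis and amino acid transport lay higher; 10 rose, and 22 rose adjusted over the list alone. Srm, which encodes spermidine synthase, rose from 30.7 ± 2.39 to 54.9 ± 2.92 TPM, and the nucleolar genes Nop56, Nop16 and Ppan had log2 fold changes of 0.63, 0.61 and 0.64.

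The 3 lists were higher by camera, with adjusted p of 1.5e-13 for G2 and mitosis, 1.9e-10 for S phase and 1.9e-12 for ribosome biogenesis. None of the 3 calls held with an estimated correlation (adjusted p = 0.29 for each). The number of members that rose was 0 to 23, 0 to 24 and 0 to 22 with single libraries left out, with the highest number without LAG3+ replicate 2 in each case. Of the genes named in these lists, each lost its call without at least 1 of the LAG3- libraries.

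Smaller shifts appeared in metabolic lists. Of 17 glycolysis and glucose transport genes, 2 rose (7 adjusted over the list alone): Ldha, which encodes a lactate dehydrogenase subunit, from 621 ± 30.4 to 840.1 ± 40.3 TPM and Pgk1 from 181 ± 6.52 to 233 ± 9.40 TPM. Of 20 cholesterol and fatty acid synthesis genes, 2 rose (6 adjusted over the list alone), among them Fdps from 51.5 ± 4.53 to 71.1 ± 4.23 TPM. Of 20 endoplasmic reticulum chaperone and unfolded protein response genes, 0 passed over all genes in limma, 4 rose adjusted over the list alone and 7 were higher at an unadjusted p under 0.05; the chaperone genes Calr and Hspa5 were 811 ± 33.2 against 646 ± 33.9 TPM and 668 ± 62.3 against 516 ± 9.24 TPM (adjusted p = 0.056 and 0.059). These 3 lists were higher by camera, with adjusted p of 0.0069, 0.00074 and 0.0088, and lost the call with an estimated correlation (adjusted p = 0.64, 0.60 and 0.43). Without LAG3+ replicate 2 they had 9, 11 and 9 higher members, and with any other single library left out each had 0. Without any 1 of the LAG3- libraries Ldha, Pgk1 and Fdps did not pass. Of 35 oxidative phosphorylation genes, 0 passed in limma, over all genes or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05; Cox5a and Cyc1 had log2 fold changes of 0.23 and 0.24 (adjusted p = 0.11 and 0.17). That list did not pass (adjusted p = 0.996), with a median of 0.02 and a mean of 0.0092 while the test statistic pointed down; without LAG3+ replicate 2 it passed as lower (adjusted p = 0.032), with 3 members higher and 3 lower.

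**Figure D2:**
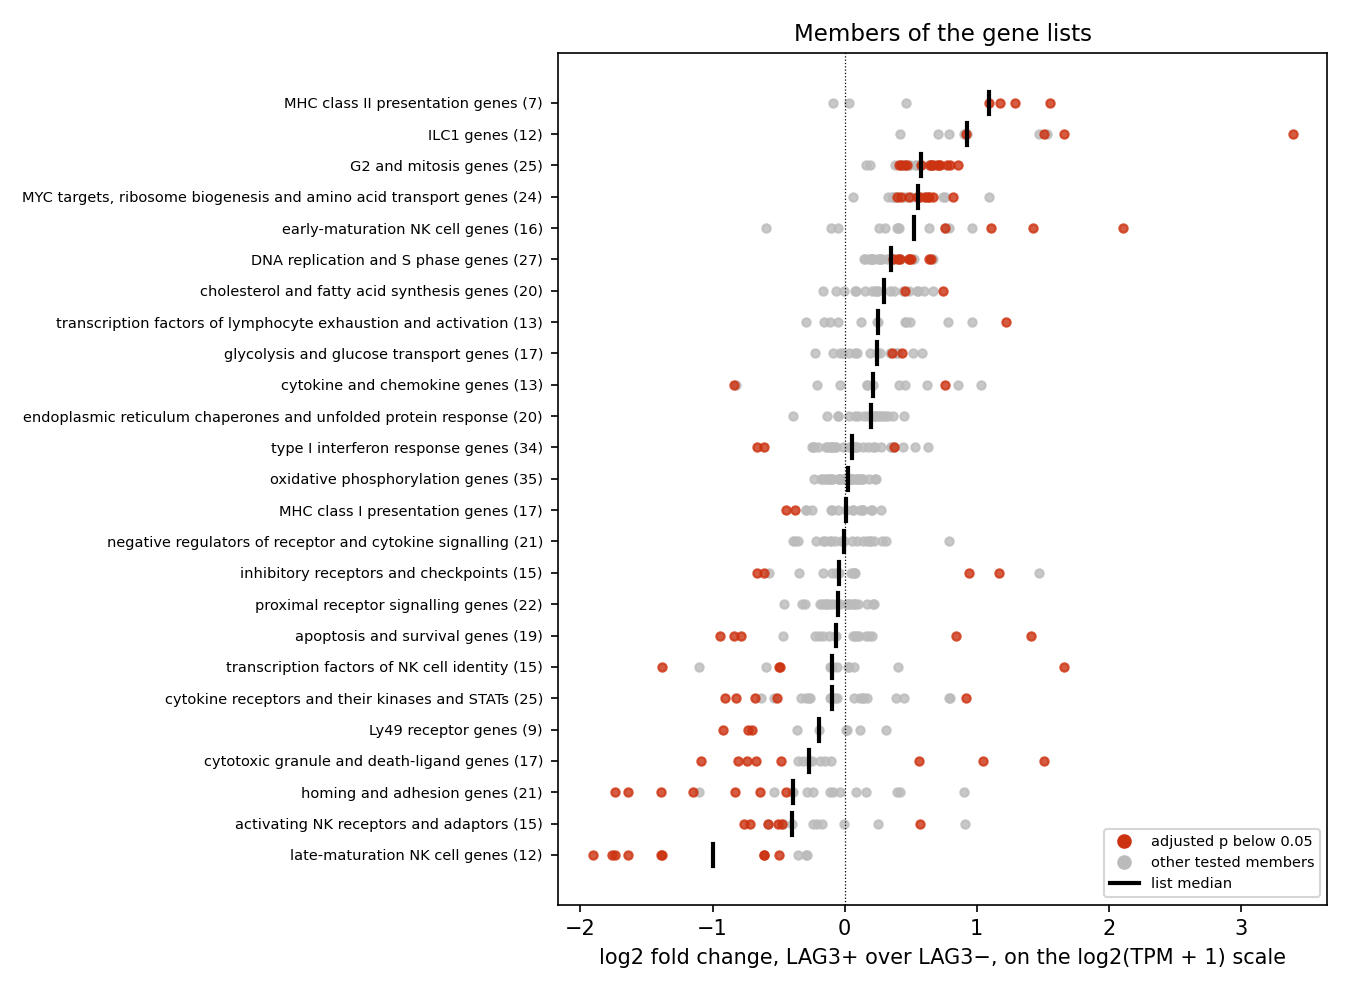
Log2 fold change, LAG3+ over LAG3-, on the log2(TPM + 1) scale for each tested member of 25 gene lists, with genes at adjusted p below 0.05 in red, other members in grey and the list median as a black bar; the number of tested members stands in brackets. All 12 late-maturation genes lie below 0 and all 25 G2 and mitosis genes above 0.

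Type I interferon response genes showed no list-wide difference 2 days after poly(I:C). Of 34 tested, 1 rose and 2 fell, also adjusted over the list alone. Isg15 rose from 48.6 ± 1.46 to 63.3 ± 2.58 TPM, while Oasl2 fell from 10.5 ± 0.779 to 6.23 ± 0.291 TPM and Ifit3 from 15.2 ± 1.68 to 9.59 ± 0.429 TPM. Camera gave an adjusted p of 0.996. The 3 calls held without LAG3+ replicate 2, when 5 members rose and 2 fell, and none of them held without any 1 of the other libraries. Of 7 tested MHC class II genes, 4 rose (5 adjusted over the list alone): the invariant chain gene Cd74 from 15.1 ± 1.49 to 46.8 ± 8.56 TPM (log2 fold change 1.56, SE 0.16, adjusted p = 0.0039), H2-Ab1 from 5.19 ± 0.559 to 14.2 ± 1.43 TPM, H2-Eb1 from 4.46 ± 0.595 to 10.6 ± 0.257 TPM and H2-Aa from 5.03 ± 1.07 to 12.7 ± 2.88 TPM. Markers of other cells stood beside this: the sum of B cell markers was 413 ± 55.6 against 233 ± 11.4 TPM and that of monocyte and macrophage markers 88.9 ± 9.01 against 142 ± 6.03 TPM. Most of the B cell sum was Ighm (248 ± 25.2 against 185 ± 6.80 TPM) and Cd22 (154 ± 34.1 against 39.3 ± 4.56 TPM). Cd79b was 5.49 ± 0.672 against 3.71 ± 0.212 TPM and Cd79a 0.607 ± 0.361 against 0.623 ± 0.142 TPM. The MHC class II list was higher by camera (adjusted p = 0.00027) but not with an estimated correlation (adjusted p = 0.26), and 2 to 5 members rose with single libraries left out; Cd74 and H2-Ab1 passed each time, H2-Eb1 did not without LAG3- replicate 2, and H2-Aa passed only without LAG3+ replicate 2. Of 17 MHC class I presentation genes, 2 fell, also adjusted over the list alone, H2-D1 from 2987 ± 105 to 2303 ± 109 TPM and H2-T23 from 468 ± 25.9 to 343 ± 8.62 TPM. That list did not pass (adjusted p = 0.33; median 0.01, mean -0.04), and both genes failed to pass without any library other than LAG3+ replicate 2.

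Apoptosis and survival genes moved both ways. Of 19 tested, 2 rose and 3 fell, also adjusted over the list alone. Bcl2a1d, an anti-apoptotic gene with near-identical copies between which reads can be split, rose from 5.97 ± 0.224 to 17.7 ± 2.82 TPM and passed with each library left out in turn. The survival gene Bcl2 fell from 32.0 ± 3.04 to 18.2 ± 2.72 TPM, the pro-apoptotic gene Bbc3 from 28.9 ± 3.32 to 14.6 ± 3.05 TPM and the cell cycle inhibitor gene Cdkn1a from 23.5 ± 1.01 to 12.7 ± 1.17 TPM, and each lost its call without any 1 of the LAG3- libraries. The list did not pass by camera (adjusted p = 0.51), and 1 to 4 members rose and 0 to 3 fell with single libraries left out.

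Transcripts typical of other cell types were compared in the same way. Of 9 tested T cell markers, 3 rose (5 rose and 1 fell adjusted over the list alone): Cd3g from 23.2 ± 2.93 to 71.3 ± 2.34 TPM, Cd3d from 20.1 ± 5.12 to 52.7 ± 8.67 TPM and Trbc2 from 373 ± 12.2 to 506 ± 20.4 TPM, while Trbc1 was 743 ± 109 against 546 ± 45.8 TPM (adjusted p = 0.082). Of 5 tested B cell markers, Cd22 and Ighm rose, Ighm from 185 ± 6.80 to 248 ± 25.2 TPM (3 rose and 1 fell adjusted over the list alone). Of 3 tested plasma cell markers, 1 rose, also adjusted over the list alone: Jchain, the joining chain of polymeric immunoglobulin, from 1.71 ± 0.545 to 5.90 ± 0.164 TPM; Igha was 2.96 ± 2.75 TPM in LAG3+ and listed at 2.62, 0 and 0 TPM in LAG3- libraries. Of 4 tested monocyte and macrophage markers, the lysozyme gene Lyz2 fell from 93.0 ± 5.00 to 49.2 ± 10.8 TPM (2 fell adjusted over the list alone), and Cd68 was 31.2 ± 4.27 against 36.9 ± 2.87 TPM. By camera the T cell (adjusted p = 0.0088) and plasma cell lists (0.027) were higher, the monocyte list was lower (0.0042) and the B cell list did not pass (0.13); with an estimated correlation none of the 3 calls held (adjusted p = 0.29 for each). The T cell and plasma cell calls were also lost without LAG3+ replicate 2 (adjusted p = 0.10 and 0.077). Cd3g and Cd22 passed with each library left out in turn; Ighm, Trbc2, Lyz2, Cd3d and Jchain each lost the call without LAG3- replicate 3.

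The remaining marker lists gave few calls. Of 3 tested platelet markers, Gp1bb fell, while Itgb3 was 10.4 ± 2.95 against 6.63 ± 0.131 TPM (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.51). Neutrophil, dendritic cell and erythroid lists had 3, 3 and 4 tested members, with 0 calls in limma, adjusted over the list alone too, and 0 members at an unadjusted p under 0.05 (camera adjusted p = 0.44, 0.63 and 0.51). S100a8, S100a9 and Csf3r were at most 6.58 TPM on average in either fraction, and Naaa and Tcf4 at most 18.3 TPM. The haemoglobin genes Hbb-bs and Hba-a2 differed between the libraries within both fractions. In replicates 1, 2 and 3 Hbb-bs held 106, 29.4 and 3.76 TPM in LAG3- cells and 70.4, 20.3 and 0.453 TPM in LAG3+ cells. Mast cell and endothelial lists had 1 tested member each, too few for a list test. Cpa3 was 2.45 ± 0.471 against 1.30 ± 0.208 TPM (limma adjusted p = 0.099). With 1 member, adjustment over the list alone leaves its unadjusted limma p of 0.012 unchanged. Pecam1 was 84.7 ± 14.6 against 79.7 ± 4.57 TPM (limma adjusted p = 0.81). Mcpt8 and Egfl7 were below the filter, at 0.700 and 0.699 TPM in LAG3+ cells. Immediate-early and heat-shock genes, which respond to handling of cells, had 0 calls among 19 in limma, adjusted over the list alone too, and 2 higher and 2 lower members at an unadjusted p under 0.05 (camera adjusted p = 0.74); Hspe1 and Ier3 were 186 ± 33.4 against 137 ± 9.34 and 0.719 ± 0.257 against 1.71 ± 0.426 TPM.

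**Figure D3:**
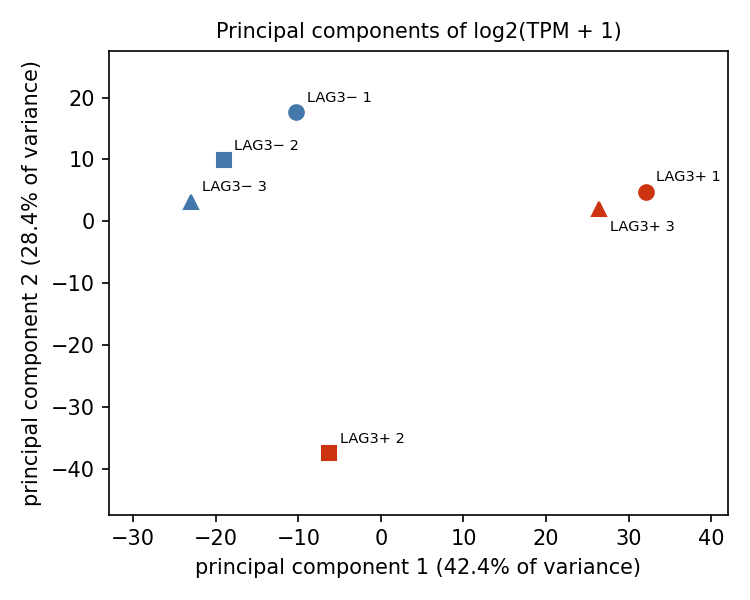
First 2 principal components of log2(TPM + 1) over the genes tested, holding 42.4% and 28.4% of the variance, with LAG3- libraries in blue, LAG3+ libraries in red and symbols for the replicate number. LAG3+ replicates 1 and 3 lie at 32.1 and 26.5 on the first component and LAG3+ replicate 2 at -6.26, with -37.5 on the second.

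Differences were tested with limma on log2(TPM + 1) over genes with a mean of at least 1 TPM, and genes at a Benjamini-Hochberg adjusted p below 0.05 were counted as changed. Of the genes tested, 2595 had an unadjusted p under 0.05, and in 3343, or 29.4%, the 3 LAG3+ values did not overlap the 3 LAG3- values, where chance gives 10%. LAG3+ replicate 2 stood apart from the other LAG3+ libraries. Without it, 2249 genes were called higher and 840 lower, or 72.8% higher against 49.5% in the full comparison. The median log2 fold change of all genes tested then moved from 0.033 to 0.12, so the excess of higher genes came with a shift of the whole comparison. Ribosomal protein genes held 20.4% of TPM in that library, against 14.8% and 16.1% in LAG3+ replicates 1 and 3. How much of the excess reflects such composition was not tested. With any other library left out, 38 to 97 genes were higher and 51 to 163 lower. Of 90 named genes that passed, 32 did so with each library left out in turn.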

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

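Each of the 90 named genes that passed kept its direction under every alternative that tested it, and 31 of them passed under each of those. Of the 31, Cd63 and Cdh22 were not tested at a mean TPM of at least 5, nor Dennd2b and Ly6a2 with the length and GC correction. Lag3 kept its call throughout, with log2 fold changes from 2.64 to 3.16. Of 18 lists past camera, 14 passed under every alternative that tested them, and the monocyte and macrophage list among these had too few members at a mean TPM of at least 5; the transcription factors of NK cell identity, Ly49, plasma cell and T cell lists did not. With an estimated correlation in camera, only the late-maturation list of these 18 kept its call (adjusted p = 0.042). Limma's fry, unadjusted over lists, gave p of 7.2e-06 for that list and 9.96e-05 for MHC class II genes. In limma's fry the cytotoxic, ribosome biogenesis, S phase, mitosis and early-maturation lists had p of 0.0023, 0.0042, 0.0049, 0.0060 and 0.0073. Only NK cell identity, Ly49, glycolysis and cholesterol lists of the 18 had fry p above 0.05 in limma (0.29, 0.081, 0.079 and 0.077). For inhibitory receptors, negative regulators and oxidative phosphorylation fry pointed up and camera down. The counts of genes moved most. Those higher and lower were 155 and 184 with no filter on low values, where more genes are tested, 583 and 664 with quantile normalization, 2389 and 1022 with library weights, and 791 and 773 with the length and GC correction, which was chosen after the data were seen. The 10885 genes of that correction gave 353 and 364 when tested without it. With the replicate block 187 and 182 passed, against 377 and 384 without it. Genes at least 2-fold higher numbered 54 with no filter, 51 at a mean TPM of at least 5, where fewer genes are tested, and 176 with library weights. With single libraries left out, genes higher ranged from 38 (LAG3- replicate 3) to 2249 (LAG3+ replicate 2), genes lower from 51 to 840, genes at least 2-fold higher from 34 to 177 and at least 2-fold lower from 38 to 96. Apart from the number of genes or libraries, the cause was not tested. Depth is unknown, so whether a low value rests on few reads cannot be told.

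The replicate numbers do not pair the samples by the rule fixed for it: deviations of libraries that share a number correlated at 0.348, -0.0045 and -0.0072, and only LAG3+ replicate 1 correlated best with the LAG3- library of its number. Haemoglobin transcripts did fall from replicate 1 to 3 in both fractions, and immediate-early transcripts were higher in replicate 1 of both, a hint from the data and not from the design. The block ended 23 named calls by adjusted p at unchanged fold changes, and the erythroid list passed with it (adjusted p = 0.0050).

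These medians or log2 fold changes turned sign, and the cause was not tested. With library weights they were 0.0051 for Ifng, 0.068 for inhibitory receptors, 0.0017 for transcription factors of NK cell identity, 0.013 for cytokine receptors, 0.057 for proximal signalling, 0.17 for negative regulators, -0.038 for oxidative phosphorylation, 0.076 for apoptosis, 0.42 for immediate-early and 0.0088 for dendritic cell genes. With no filter they were 0.070 for inhibitory receptors, 0.0081 for Ly49, 0.00070 for negative regulators and 0.13 for dendritic cell genes, and at a mean TPM of at least 5 it was 0.026 for negative regulators. Oxidative phosphorylation and MHC class I genes were at -0.017 and -0.028 with median-of-ratios scaling, -0.020 and -0.018 with quantile normalization, and -0.019 and -0.010 with the length and GC correction.

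With single libraries left out, lowest and highest values were -0.50 and 0.10 for Ifng, -2.16 and 0.65 for Hbb-bs, -2.12 and 0.60 for Hba-a2, -0.0066 and 0.22 for Pecam1, and -0.72 and 0.084 for S100a9. For lists they were -0.14 and 0.095 (inhibitory receptors), -0.18 and 0.025 (NK cell identity), -0.16 and 0.045 (cytokine receptors), -0.084 and 0.068 (proximal signalling), -0.085 and 0.18 (negative regulators), -0.042 and 0.13 (interferon), -0.037 and 0.043 (oxidative phosphorylation), -0.012 and 0.033 (MHC class I), -0.13 and 0.11 (apoptosis), -0.62 and 0.35 (immediate-early), -0.22 and 0.049 (dendritic cell) and -1.96 and 0.62 (erythroid).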

Other observations

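The gene families below, the tests on dendritic cells, on monocytes and macrophages, on plasma cells, on the early-maturation profile and on LAG3- cells in LAG3+ replicate 2, the sums of markers under 1 TPM, and the length and GC correction were chosen only after the result was seen. Since the 9 families were picked from the values, no test of them as families is given. All 10 tested T cell receptor gamma genes rose, and their sum was 392 ± 174 against 55.8 ± 10.8 TPM. Trgc4, a constant region gene, rose from 10.9 ± 2.03 to 98.3 ± 19.9 TPM, and Trgj1 and Trgj2 were listed at 0 in the LAG3- libraries. Gamma genes resemble one another, so reads can be split between copies. Of 8 T cell receptor alpha and delta variable genes 2 rose, while their median log2 fold change was -0.34 and their sum 247 ± 9.27 against 308 ± 9.24 TPM. Of 51 immunoglobulin variable genes and Igkc, 9 rose, Igkc from 29.8 ± 6.13 to 121 ± 32.8 TPM.

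Of 14 Notch pathway genes, Dll1, Dtx1 and Dtx3 rose and Nrarp fell. Dtx1, which encodes a ubiquitin ligase that acts on Notch, rose from 46.8 ± 4.45 to 132 ± 19.8 TPM, and Nrarp, a Notch target gene, fell from 61.8 ± 1.46 to 42.2 ± 5.32 TPM. Of 11 adhesion G protein-coupled receptor genes, Adgrg3, Adgrg5 and Adgrl1 rose. Of 14 purinergic genes, P2rx7 rose while Entpd1 and P2ry14 fell. Kcnj8 and Kcnip3 fell among 11 potassium channel genes. Mitochondrially encoded genes, whose share can also follow RNA quality, summed to 26539 ± 6958 against 17868 ± 3093 TPM with a median log2 fold change of 0.58; of 13 tested, 0 passed in limma and 8 were higher at an unadjusted p under 0.05. Of 122 ribosomal protein genes, 2 rose, with a median of -0.077.

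MHC class II and immunoglobulin transcripts were higher in LAG3+ cells. More B cells would raise B cell genes as much as Cd74, but in the highest of 9 pairings of libraries the log2 ratio of the B cell gene sum was below that of Cd74 by a difference of -0.83, or -1.004 without Ighm and -0.62 for markers under 1 TPM in LAG3- cells, which speaks against B cells as the source of the whole MHC class II difference. Monocytes and macrophages gave -1.07 for their markers under 1 TPM and -1.72 for all of their markers, which speaks against them in the same way. Dendritic cells gave -1.38 for all markers, but 0.15 for those under 1 TPM, which summed to 2.68 ± 0.621 against 1.26 ± 0.138 TPM, so dendritic cells could be a source and stay open. For the immunoglobulin part plasma cells stay open too: their gene sum had a log2 ratio of 0.82, below that of Igkc (2.02), while Jchain rose by 1.79, near Igkc; the sort for CD11b+ NK cells is meant to remove both cell types, and its gates are not given in the sources used here.

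CD3 and T cell receptor gamma transcripts were higher in LAG3+ cells. More T cells would raise other T cell genes as much as Cd3g, but the highest of 9 pairings gave a difference of -0.91. The genes summed include Cd4, Cd8b1 and Themis, chiefly genes of T cells with alpha-beta receptors. The test therefore says less about T cells with gamma-delta receptors. That sum is mostly Cd28, at 18.3 ± 5.51 against 16.5 ± 3.37 TPM, and for the 7 markers under 1 TPM in LAG3- cells, 5.66 ± 1.45 against 3.17 ± 0.580 TPM, the highest difference was -0.30, which speaks less strongly against T cells as the source of the whole difference and leaves a part open. Cd3e, which T cells hold beside Cd3g, was 7.90 ± 2.25 against 6.84 ± 0.951 TPM, and Trdc, the constant region of the delta chain, was 28.2 ± 0.337 against 37.1 ± 1.77 TPM (adjusted p = 0.053). The transcripts may instead be part of the early-maturation and ILC1 profile. Camera with an estimated correlation gave those lists an adjusted p of 0.29. Neither list holds CD3 or T cell receptor genes, so that test cannot decide the question, which stays open.

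LAG3+ replicate 2 lay apart from the other LAG3+ libraries. Its log2(TPM + 1) values correlated best with LAG3- replicate 3, at 0.977. The values were 0.975 and 0.972 with LAG3+ replicates 3 and 1. LAG3- cells mixed into LAG3+ replicate 2 would pull higher and lower genes back alike. It reached 0.165 of the difference in genes that rose and 0.958 in genes that fell, a gap of 0.793. These shares were taken without scaling between libraries. The median-of-ratios factor of LAG3+ replicate 2 was 0.892, against 1.09 in each of LAG3+ replicates 1 and 3. A downward shift of a whole library lowers the share in risen genes and raises that in fallen genes. The gap therefore cannot decide whether this library held LAG3- cells. Noise of weakly expressed genes at a lower depth would leave abundant genes alone, but in the 2838 genes with the highest mean TPM its deviation was 1.57 times that of the other LAG3+ libraries. After a correction for transcript length and GC content 0.809 of its distance remained (95% bootstrap interval over genes 0.796 to 0.820). Most of the distance therefore did not follow a smooth length and GC trend, and a smaller part may have. The interval resamples genes and measures no spread between libraries. Spearman correlations of its deviation were -0.319 with length and 0.293 with GC content. Those with GC content were -0.425 and 0.389 in LAG3- replicates 2 and 3. Whether cell state, handling or library preparation set this library apart was not tested.

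Only 10 splits of 6 libraries into 3 and 3 exist, too few for a share below 0.05. The real split ranked 1 of 10 in each count, with 761 genes against at most 2, 170 genes of at least 2-fold against at most 2, and 18 lists against at most 16. At an unadjusted p under 0.05 in limma the gap was smaller. The real split gave 2595 genes, and LAG3- replicate 1 with LAG3+ replicates 1 and 3 against the rest gave 2084. Values of 2 gene groups varied with the replicate number in both fractions: the haemoglobin sum was 274, 75.8 and 10.0 TPM in LAG3- and 193, 50.4 and 2.95 TPM in LAG3+ replicates 1, 2 and 3, and median deviations of immediate-early genes were 0.87, -0.39 and -0.35 in LAG3- and 0.78, -0.57 and -0.62 in LAG3+ replicates 1, 2 and 3.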
